A study of Homo sapiens with 4 samples.

How the data were processed

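Polyadenylated RNA of 4 cell line libraries was measured by sequencing. Per the labels' protocols, cells grew in DMEM with 10% FBS, RNA was taken with Trizol and libraries were made with the KAPA Stranded mRNA-Seq kit. Per the labels, the libraries are MCF7 and ZR75 (controls) and MCF7BQ and ZR75BQ (overexpression of BQ323636.1), all of batch 1, with 1 library in each of 4 groups. Per the submitters' processing notes, STAR and GRCh38.p14 were used, with no version or role stated. The counting tool, the annotation release and the normalization tool are not given in the sources used here. By identifier, 95.9% of the transcripts have the same versioned entry in GENCODE 29, with the same GRCh38 coordinates for 100% of those, and gene names and positions follow the deposited table.

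The authors deposited 3 kinds of values per transcript. Per the file headers, the first is TPM, and the values of each library sum to about 1000000. The second is, per the file headers, normalised read counts, a signal that the authors scaled. Its values are fractional read estimates times 1 constant per library (0.925 to 1.04), seen as a repeated smallest step. The third is a score: the deposited posterior and real fold changes, PPDE and FDR of a comparison of the BQ-labelled with the control-labelled libraries. In those columns FDR equals 1 - PPDE. The real fold change is the larger over the smaller group mean of normalised reads, with 0.01 added to each. This held within a relative 0.01 for 100% of the compared transcripts. The fold carries no direction, which is listed apart. The 4 single-library files hold the same values as the table of the whole series.

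Transcript values were summed per gene (199348 transcripts, 60725 genes). Normalised reads summed to 17826529 to 20774655 per library. The 10 highest genes held 5.44 to 7.48% of the reads and mitochondrially encoded genes 4.55 to 6.14%. Summed gene values divided by the step were whole within 0.05 for 86.6 to 87.1% of genes, so the values were not taken as counts. The design, fixed before the data were examined, had planned a count-based test. For normalized values it had named limma on log2(value + 1), which was used instead.

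Genes with at least 10 normalised reads in at least 2 libraries were tested (16727 genes). limma 3.58.1 in R 4.3.3 fitted log2(normalised reads + 1) on cell line and state (eBayes with trend, 1 residual degree of freedom, 3.61 prior degrees of freedom). Benjamini-Hochberg adjusted p below 0.05 was the threshold. The line term of the same fit compared the lines. With 1 library per group, each pair of libraries got no test. Its log2 ratio was taken after adding 2 reads, for genes with at least 1 read per 1000000 in either library and 10 reads over the pair, and 2-fold was the threshold. The pairing of libraries is by the cell line in the labels. Agreement between pairs was described by Pearson r, Spearman rho and the overlap independent lists would give. Comparisons of both control-labelled and of both BQ-labelled libraries were added after the data were seen.

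Sets of genes came from 37 lists (560 genes, 558 matched), and the 36 lists with at least 5 tested members were tested. limma's camera, with a preset correlation of 0.01, compared each list with all other genes, and was repeated with an estimated correlation. The repeat rested on 1 residual degree of freedom, which left it little power for any list. Its p-values are therefore no evidence against a list. fry asked whether a list's genes move on balance one way. Members were also counted with p-values adjusted over the list alone. For single pairs, a list's median log2 ratio was placed among 10000 random lists matched on mean expression in 20 bins. Random lists draw genes singly, while members of a list can vary together, so these percentiles are a description and can overstate small shifts. Lists of embryonic kidney cell line markers and of genes deleted in MCF-7 were added after the data were seen and are used only in the closing section.

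Genes were named by a rule: NCOR2; the 12 largest log2 differences in each direction over both lines and in each pair; 4 members with the smallest p of each list described; 6 genes with opposite changes; and 8 between the lines. Unnamed loci and pseudogenes were left out, and a value of at least 1 (both lines) or 5 (pairs) per 1000000 reads was required. For the comparisons added later the largest log2 ratios were named, 12 for the control-labelled libraries.

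The test was checked on simulated data: 200 of 16727 genes were changed in libraries of the same depth, with a simulated spread of 0.08 on the natural log scale. At 2-fold 97% were recovered, and at 4-fold and 16-fold 100%, all in the right direction, with 0 unchanged genes called. The changed genes were drawn from better-covered genes only, and every gene had the same spread. In the data 77.5% of genes passed, some of them near 0 in a state, so these rates do not carry over to the data. Alternatives covered limma without trend, robust spread, median-of-ratios factors recomputed on the normalised reads, equal totals, TPM, other filters, pseudocounts, prior reads and thresholds, no line term, transcripts in place of genes, and each library left out. With 3 libraries the line term had to go too, and the state left with 1 library was assumed to vary like the other. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.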

Results

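The deposited table covered 4 polyadenylated RNA libraries, labelled MCF7, ZR75, MCF7BQ and ZR75BQ. The names stand for MCF-7 and ZR-75-1, 2 estrogen receptor-positive luminal breast cancer lines, as controls or with overexpression of BQ323636.1, a splice variant of the corepressor gene NCOR2. It listed 199348 transcripts of 60725 genes, and between 22006 and 22610 genes were above 0 in each library. Normalised reads summed to 20774655 (MCF7), 20227449 (ZR75), 18114836 (MCF7BQ) and 17826529 (ZR75BQ). Each group held 1 library, so the lines, as labelled, served as replicates and each state had n = 2. All p-values measure only the spread between these libraries, since the labels do not state how many cultures they came from.

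NCOR2, which encodes SMRT and contains the sequence of BQ323636.1, served as the check of the labels. Its level was lower, not higher, in the libraries labelled as overexpressing the variant: 143 TPM (MCF7), 146 (ZR75), 72.1 (MCF7BQ) and 76.4 (ZR75BQ). The group means were 145 ± 2.60 and 74.2 ± 3.09 TPM (SD, n = 2 libraries each), and the log2 difference was -1.19 (SE 0.0427, adjusted p = 4.88e-05, limma with Benjamini-Hochberg). Of 24 NCOR2 transcripts (chromosome 12, 124324415 to 124567589, GRCh38), 12 reached 5 TPM in at least 1 library, with 9 of them lower and 3 higher in the BQ-labelled libraries. One of them, ENST00000356219.7, was at 10.6 and 13.3 TPM in the control-labelled libraries and listed at 0 in both BQ-labelled ones. The table's identifiers do not tell the variant from other NCOR2 transcripts, and its own level is not given here. Because NCOR2 did not follow the labels, each direction below is between libraries as labelled, not an effect of the variant.

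Several of the genes with the largest log2 differences toward the control-labelled libraries are known from luminal breast epithelium. ESR1 (chromosome 6, 151656691 to 152129619), which encodes the estrogen receptor alpha, was at 127 and 108 TPM in the libraries labelled MCF7 and ZR75 and listed at 0 in both BQ-labelled libraries. The luminal keratin KRT19 was at 2754 and 2691 TPM and then listed at 0 in both. The estrogen-induced secreted protein gene TFF1 was at 2444 and 2993 TPM in the control-labelled libraries, listed at 0 in the library labelled MCF7BQ and at 0.21 TPM in the one labelled ZR75BQ. AGR2 (980.5 and 875 TPM), MLPH (439.8 and 446), FXYD3 (852 and 748) and the epithelial transcription factor gene GRHL2 (84.6 and 80.1) were all listed at 0 in both BQ-labelled libraries. The same held for KRT80 (110.3 and 135 TPM) and MAL2 (133 and 137), and for genes of other kinds, the ligand gene SHH (124 and 111), the matrix gene THBS1 (96.5 and 78.9) and the adhesion gene DSCAM (50.2 and 44.3).

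Among the genes higher in the BQ-labelled libraries, IRS4 stood first (X chromosome, 108732482 to 108736409). It encodes an insulin receptor substrate and went from 0.04 TPM and a listed 0 to 479 and 646 TPM in the libraries labelled MCF7BQ and ZR75BQ. GSTP1, a glutathione transferase gene, was listed at 0 and at 0.14 TPM in the control-labelled libraries against 486 and 451 TPM. The peroxidase gene GPX1 was at 0.07 TPM and listed at 0 against 259 and 244 TPM. The membrane linker gene MSN was listed at 0 and at 0.05 TPM against 82.7 and 88.1 TPM. HOXD13 (75.2 and 78.9 TPM), SLC6A15 (56.5 and 61.1), DZIP1 (39.4 and 44.2), C17orf51 (25.3 and 30.6), the cyclin gene CCND2 (21.6 and 22.7) and ZFHX4 (16.5 and 20.77) were listed at 0 in both control-labelled libraries. The matrix genes NID1 (39.3 and 45.2 TPM) and VCAN (25.2 and 32.0 TPM) were at most at 0.01 TPM there.

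**Figure D1:**
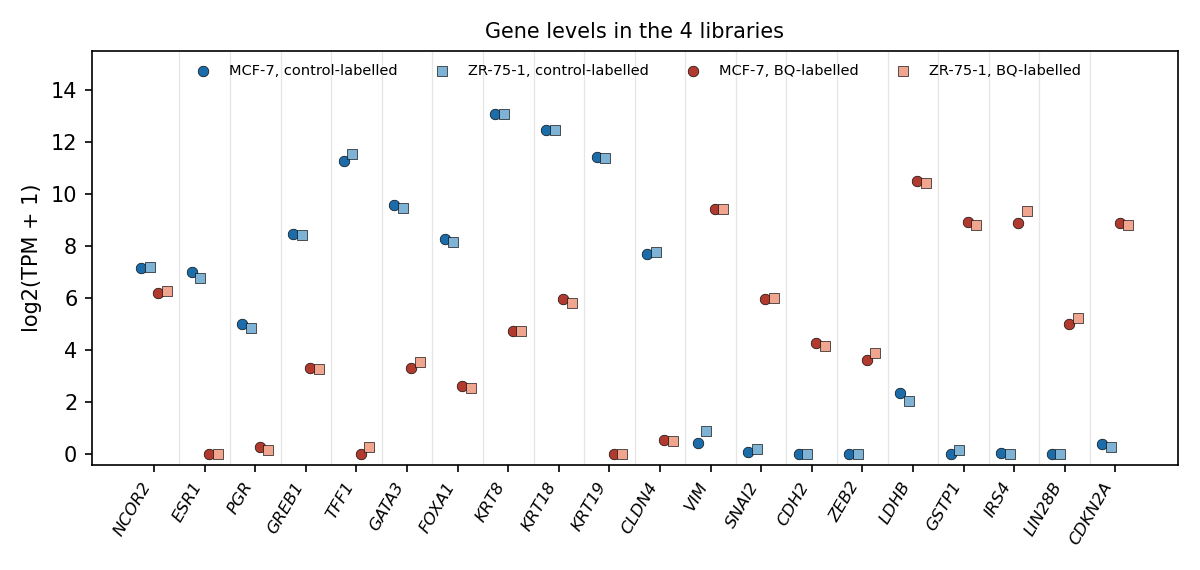
Levels of 20 genes in each of the 4 libraries, as log2(TPM + 1), 1 dot per library (n = 1 library per group). NCOR2 is the label check; the other genes mark luminal epithelium, mesenchymal cells or the largest differences, and were chosen for the drawing after their values were seen.

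In all, 12959 of 16727 genes (77.5%) passed an adjusted p below 0.05 in limma with Benjamini-Hochberg, 6689 higher and 6270 lower in the BQ-labelled libraries. Of these, 7829 also differed at least 2-fold (4033 higher, 3796 lower) and 2575 at least 10-fold (1259 higher, 1316 lower). The adjusted p was 1.31e-05 for ESR1, 8.59e-06 for KRT19 and 4.60e-05 for IRS4. The deposited scaling sets the zero point: equal totals moved the median gene by 0.19 log2 and TPM by 0.17 toward the BQ-labelled libraries, against -0.03 for median-of-ratios. Log2 differences of genes near 0 are understated, because 1 read was added before the log.

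Gene lists fixed beforehand covered epithelial and luminal identity. All 15 tested epithelial junction and keratin genes were lower in the BQ-labelled libraries, 15 also when adjusted over the list alone, with a median log2 difference of -8.28. KRT8 went from 8624 ± 47.6 to 25.9 ± 0.269 TPM (log2 -8.74, SE 0.0437), KRT18 from 5626 ± 48.0 to 58.3 ± 4.49 TPM (-6.88, SE 0.0579) and the claudin gene CLDN4 from 212 ± 8.27 to 0.445 ± 0.0212 TPM (-8.05, SE 0.119; mean ± SD, n = 2 libraries each). Against all other genes the list was lower (camera in limma, adjusted p = 2.36e-07; adjusted p = 0.823 with an estimated correlation). Of 11 luminal identity factors, 9 were lower and 2 higher, also when adjusted over the list alone, with a median of -6.88 (camera adjusted p = 0.00198; adjusted p = 0.823 with an estimated correlation). KRT8 and KRT18 belong to both the epithelial and the luminal list, so the results of these lists are not separate evidence. GATA3 fell from 735 ± 37.7 to 9.88 ± 1.38 TPM and FOXA1, whose product opens chromatin for the estrogen receptor, from 295 ± 17.84 to 5.035 ± 0.177 TPM.

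Estrogen-induced genes were lower throughout: 24 of 24, and 24 when adjusted over the list alone, with a median log2 difference of -4.75 (camera adjusted p = 3.61e-10; adjusted p = 0.823 with an estimated correlation). GREB1 went from 348 ± 3.59 to 8.98 ± 0.198 TPM (log2 -5.61, SE 0.0438) and the cyclin D1 gene CCND1 from 479 ± 4.51 to 10.53 ± 0.559 TPM (-5.61, SE 0.0461). CTSD fell from 1785 ± 35.7 to 134.2 ± 4.69 TPM and IGFBP4 from 266 ± 5.02 to 4.22 ± 0.127 TPM. Among 25 nuclear receptor genes 15 were lower and 7 higher, also when adjusted over the list alone, with a median of -0.91 (camera adjusted p = 0.0886; adjusted p = 0.823 with an estimated correlation). The progesterone receptor gene PGR fell from 29.8 ± 2.17 to 0.18 ± 0.0566 TPM, RXRA from 137 ± 5.39 to 15.97 ± 1.38 TPM and NR2F2 from 318 ± 36.3 to 48.5 ± 1.95 TPM. Of the 7 genes of the NCoR/SMRT corepressor complex, 4 were higher and 3 lower, also when adjusted over the list alone. Their median was 0.24 and their mean -0.30 (camera adjusted p = 0.940; adjusted p = 0.990 with an estimated correlation). Beside NCOR2, CORO2A (log2 -1.70, SE 0.0910) and TBL1X (-0.74, SE 0.0503) fell, while the deacetylase gene HDAC3 (0.65, SE 0.0567) rose.

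Mesenchymal and fibroblast markers went the other way for most members: 9 of 13 were higher and 2 lower, or 9 and 3 when adjusted over the list alone, with a median log2 difference of 6.59 (3.30 on log2(TPM + 1)). Their camera adjusted p was 0.0585 (adjusted p = 0.823 with an estimated correlation). The intermediate filament gene VIM went from 0.62 ± 0.354 to 692 ± 3.68 TPM (log2 9.94, SE 0.332), SNAI2 from 0.11 ± 0.0566 to 62.8 ± 1.36 TPM and CDH2 from 0.01 ± 0.0141 to 17.6 ± 0.976 TPM. ZEB2, a repressor of epithelial genes, was listed at 0 in both control-labelled libraries and at 11.3 and 13.8 TPM in those labelled MCF7BQ and ZR75BQ. TGF-beta target genes were lower in 10 of 11 cases and higher in 1, also when adjusted over the list alone, with a median of -2.06, or -0.94 and 8 lower on log2(TPM + 1) (camera adjusted p = 0.0213; adjusted p = 0.823 with an estimated correlation). PMEPA1 fell from 61.9 ± 4.31 to 8.13 ± 1.43 TPM, TGFBI from 15.4 ± 1.07 to 0.045 ± 0.0636 TPM and LTBP3 from 60.5 ± 2.36 to 16.6 ± 1.14 TPM.

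Fatty acid synthesis genes were higher in 8 of 10 cases and lower in 1, also when adjusted over the list alone, with a median log2 difference of 0.79 (camera adjusted p = 0.0469; adjusted p = 0.823 with an estimated correlation). SCD, the stearoyl-CoA desaturase gene, rose from 57.8 ± 4.66 to 243 ± 15.7 TPM, ACLY from 95.9 ± 3.31 to 321 ± 16.9 TPM and ACACA from 18.3 ± 1.59 to 55.7 ± 0.0849 TPM. SREBF1, whose product switches on this pathway, fell from 129 ± 0.905 to 43.9 ± 1.15 TPM. Mitochondrially encoded genes were lower in 9 of 13 cases, with none higher and 9 when adjusted over the list alone, and a median of -0.44 (-0.21 on log2(TPM + 1), with 7 lower and 4 higher). The camera adjusted p of that list was 0.0469, but 0.1004 with libraries scaled to equal totals, where 8 were lower and 2 higher (adjusted p = 0.823 with an estimated correlation). MT-CO2 had a log2 difference of -1.03 (SE 0.0515), and it did not pass in any of the 4 fits on 3 libraries. Those fits also left out the line term, and the state with 2 libraries alone gave their spread. Over the 36 lists tested, some of which share members, 1 was higher and 5 were lower by camera, and none passed with an estimated correlation. With 1 residual degree of freedom that repeat could hardly pass any list. Its unadjusted camera p was 0.104 for the epithelial genes, at an estimated correlation of -0.067, below the preset 0.01.

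In the pair labelled MCF7, ESR1, KRT19, AGR2 and TFF1 were again among the genes with the largest lower ratios. All 4 were above 100 TPM in the library labelled MCF7 and listed at 0 in the library labelled MCF7BQ. SPTSSB, which encodes a subunit of the enzyme that starts sphingolipid synthesis, went from 1149.7 to 1.30 TPM. PSAT1, an enzyme gene of serine synthesis, was listed at 0 in the library labelled MCF7 and at 130.0 TPM in MCF7BQ, CALD1 at 0 and 55.0 TPM, CXorf57 at 0 and 58.04 TPM and AGPS at 0 and 24.5 TPM. The median log2 ratio was -4.77 for estrogen-induced genes (22 of 24 at least 2-fold lower), -8.00 for epithelial genes (13 of 15) and 5.85 for mesenchymal markers (9 of 13 at least 2-fold higher). None of 10000 random lists matched on expression had a lower median than the first 2 or a higher one than the third. At least 2-fold differences numbered 7300 among 15581 genes, 3890 higher and 3410 lower in the library labelled MCF7BQ. With 1 library per group no test was possible.

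In the pair labelled ZR75, KRT19, AGR2 and ESR1 again went to a listed 0. AKR1C2, a steroid-reducing enzyme gene, went from 284 TPM in the library labelled ZR75 to a listed 0 in ZR75BQ. LIN28B, which encodes a repressor of let-7 microRNAs, was listed at 0 and at 36.9 TPM. CDKN2A, the gene of the cell cycle inhibitor p16, went from 0.21 to 452 TPM. The median log2 ratio was -4.34 for estrogen-induced genes (21 of 24 at least 2-fold lower), -8.14 for epithelial genes (13 of 15) and 6.04 for mesenchymal markers (9 of 13 at least 2-fold higher). Interferon-stimulated genes had a median of -3.35 in this pair and -0.93 in the pair labelled MCF7, and most of these genes were higher in the library labelled ZR75 than in the one labelled MCF7. Among 15815 genes, 3704 were at least 2-fold higher and 3675 at least 2-fold lower, again without a test.

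The log2 ratios of both pairs ran together over 15332 genes, with Pearson r = 0.975 and Spearman rho = 0.969. At least 2-fold higher in both pairs were 3334 genes, IRS4 and VIM among them, where independent lists would share 882. At least 2-fold lower in both were 3071 genes, ESR1 and GREB1 among them, where independent lists would share 739. Opposite 2-fold differences were seen for 11 genes higher and 1 gene lower in the pair labelled MCF7. These included the interferon-stimulated genes DDX60 (4.60 in the pair labelled MCF7 and -4.20 in the pair labelled ZR75), IFI44L (3.51 and -3.51) and IFIT1 (2.38 and -2.30). The endocytic receptor gene LRP2 (1.97 and -1.98), the lysosomal gene CD68 (1.61 and -1.86) and the ISG15-conjugating enzyme gene UBE2L6 (2.22 and -1.45) were the next largest. All these named genes were near-equal in both BQ-labelled libraries, so their opposite signs came from the control-labelled libraries. Genes are not independent replicates, so r describes these libraries. Log2 levels correlated at r = 0.971 between both control-labelled libraries and 0.989 between both BQ-labelled ones. The pairs would therefore run together however the libraries were paired, and the overlap does not show that 2 lines changed alike.

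**Figure D2:**
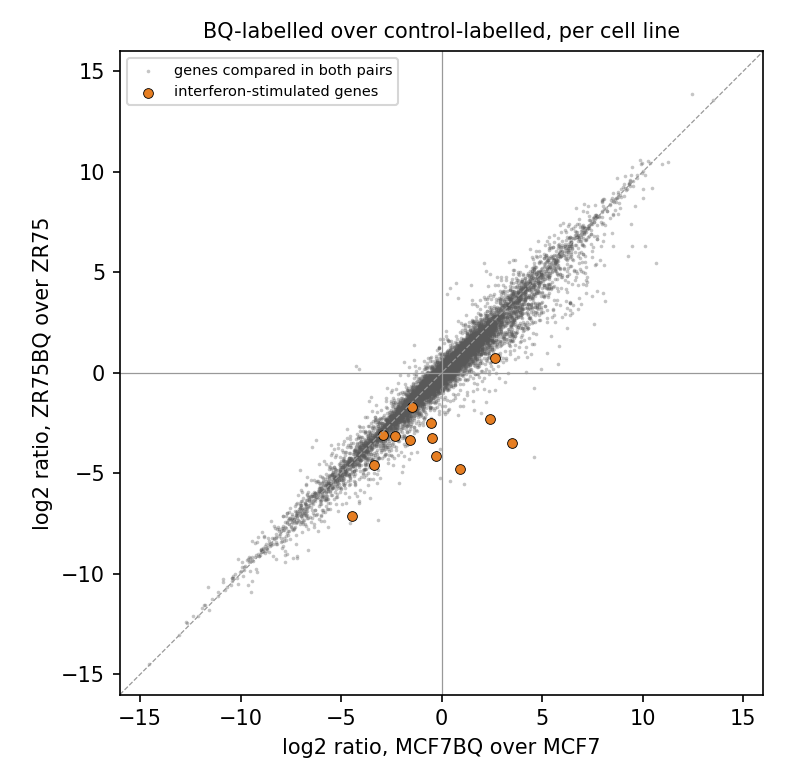
Log2 ratio of the BQ-labelled over the control-labelled library in the pair labelled MCF7 and in the pair labelled ZR75, for 15332 genes (n = 1 library per group). Orange: 13 interferon-stimulated genes. Ratios were taken after adding 2 normalised reads.

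Between the lines as labelled, ESR1, KRT19 and GATA3 hardly differed in the control-labelled libraries. ESR1 had a log2 ratio of the library labelled ZR75 over MCF7 of -0.23, KRT19 of -0.09 and GATA3 of -0.16. No gene passed an adjusted p below 0.05 for the line term in limma with Benjamini-Hochberg, while 727 had an unadjusted p below 0.05 (549 to 927 in the alternatives). With 1 residual degree of freedom, a difference seen in 1 state only enters the line term and its error alike. DDX60, at a log2 ratio of 8.64 between the control-labelled libraries, had a line term of 4.53 (SE 2.20, limma adjusted p = 0.788). The count of 0 therefore does not show that the lines are alike. Log2 levels correlated at r = 0.971 between both control-labelled libraries and 0.989 between both BQ-labelled libraries, against 0.674 within the pair labelled MCF7 and 0.678 within the pair labelled ZR75.

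Within the control-labelled libraries, a comparison added after the data were seen, interferon-stimulated genes set the library labelled ZR75 apart. IFI27 was at 3.97 TPM (MCF7) and 231 TPM (ZR75), against 2.26 and 3.18 TPM in the libraries labelled MCF7BQ and ZR75BQ. DDX60 went from 0.01 to 14.5 TPM, IFIT3 from 0.12 to 15.0, OAS2 from 0.35 to 8.76 and OASL from 0.42 to 25.4. The chemokine gene CCL5 went from 0.36 to 22.7 TPM and the stress-response gene NUPR1 from 0.93 to 45.0 TPM. IFI44L (10.0 TPM), IFI44 (10.4), XAF1 (7.18), WNT6 (5.48) and SIGLEC6 (4.69) were listed at 0 in the library labelled MCF7. Of 16 interferon-stimulated genes, 14 were at least 2-fold higher in the library labelled ZR75 and none lower, with a median log2 ratio of 2.46, above that of all 10000 matched random lists. Antigen presentation genes (median 0.66), immediate early genes (0.58), NRF2 targets (0.16) and unfolded protein and integrated stress response genes (0.16) also lay above all random lists. So, nearly, did hypoxia-induced genes (0.29, percentile 99.98) and p53 targets (0.18, percentile 99.99). At the other end, cell cycle genes (median -0.15, percentile 0) and mitochondrially encoded genes (-0.17, percentile 0.005) were lower in the library labelled ZR75. Such medians are small: 3 of 18 NRF2 targets and 2 of 17 stress response genes were at least 2-fold higher, and no cell cycle gene was 2-fold lower. Members that vary together can make such percentiles extreme. At least 2-fold differences numbered 528 higher and 46 lower in the library labelled ZR75, among 14287 genes and without a test.

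Within the BQ-labelled libraries only 131 of 14497 genes differed at least 2-fold, 70 higher and 61 lower in the library labelled ZR75BQ. Interferon-stimulated genes had a median log2 ratio of 0.11 there (percentile 97.75 of random lists). Ribosomal proteins (median -0.13, percentile 0.01) and the nuclear-encoded respiratory chain (-0.11, percentile 0.21) lay at the low end. RSC1A1 was at 6.28 TPM (MCF7BQ) and 15.2 TPM (ZR75BQ), FAM156B at 12.5 and 4.05 TPM and MAGED4, a gene of the MAGE family, at 21.5 and 12.6 TPM. Each value is a fractional estimate from 1 library, and how reads were shared among similar or overlapping loci was not examined. In the test over both lines, 9 of 16 interferon-stimulated genes were lower in the BQ-labelled libraries and 1 higher, or 8 and 1 when adjusted over the list alone. Their median log2 difference was -2.33 (camera adjusted p = 0.0559, or 0.0318 with equal totals; adjusted p = 0.867 with an estimated correlation), with the high values of the library labelled ZR75 on the control side. STAT1 fell from 55.1 ± 8.94 to 21.7 ± 1.959 TPM and ISG15 from 114 ± 59.9 to 7.76 ± 0.552 TPM.

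**Figure D3:**
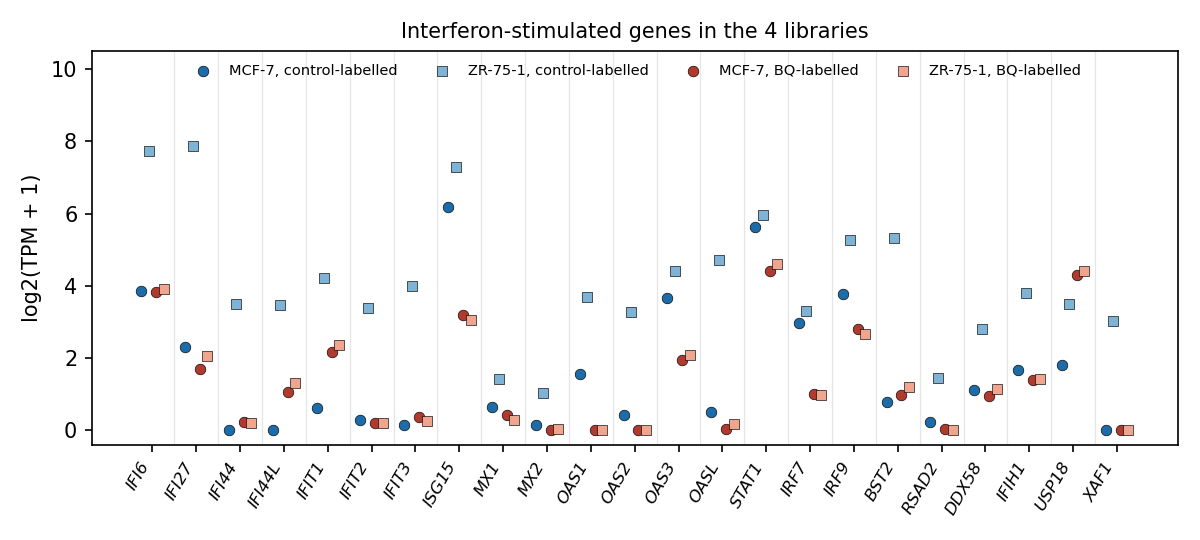
Levels of 23 interferon-stimulated genes in each library, as log2(TPM + 1), 1 dot per library (n = 1 library per group).

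The authors' deposited table gave, per transcript, its own comparison of the BQ-labelled with the control-labelled libraries over both lines. It compared 118799 transcripts and left 80549 uncompared. An FDR below 0.05 was given for 23280 transcripts of 11688 genes, 11270 of them higher and 12010 lower in the BQ-labelled libraries. The FDR was exactly 0 for 9928 transcripts. For NCOR2, 8 of the 12 transcripts that reached 5 TPM were lower at that FDR and none higher.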

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

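In this part, both tests of the interferon signal were chosen after the result had been seen. The log2 ratios here had opposite signs in both pairs, and the difference was not tested. DDX60 had a log2 ratio of 4.60 in the pair labelled MCF7 and -4.20 in the pair labelled ZR75, IFI44L 3.51 and -3.51, IFIT1 2.38 and -2.30, and UBE2L6 2.22 and -1.45. LRP2 had 1.97 and -1.98, and CD68 1.61 and -1.86. The signs came from the control-labelled side, where these genes had log2 ratios of 3.34 to 8.64 (ZR75 over MCF7). Between the BQ-labelled libraries their ratios were -0.33 to 0.19. The median log2 ratio of immune cell markers was 0.45 and -0.66, over 5 tested members (percentiles 60.6 and 24.8 of random lists). That of ABC drug transporters was 0.25 and -0.13 (percentiles 62.7 and 40.9), with 3 genes at least 2-fold higher and 2 lower in each pair. The medians of both lists lie inside the range of random lists, so their signs show no difference in direction.

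Of 16 interferon-stimulated genes, 14 were at least 2-fold higher in the library labelled ZR75 than in the one labelled MCF7, and 2 technical explanations were weighed. The library labelled MCF7 was not low throughout, since ISG15 (71.7 TPM) and STAT1 (48.8 TPM) were above the BQ-labelled libraries there too. A higher depth of the library labelled ZR75 is argued against by its read total, at most 0.974 times that of the library labelled MCF7. A difference of cell line should give genes that differ both ways. Of the genes at least 2-fold apart, 8.0% were lower in the library labelled ZR75, and 3.3% to 18.4% under other settings. No setting reached the share laid down for a difference of cell line. The main setting met the share laid down against it, but the 10-read filter alone (17.7%) and 1.5-fold (18.4%) did not. That rule was written after the result was seen, which leaves the question open. What set off the signal stays open too, since an infection, a response to introduced nucleic acid and a culture difference were not tested.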

How the results depend on the processing

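The leave-one-out fits, the TPM fit and the 2-fold threshold were chosen after the result was seen. The correlation without interferon-stimulated genes and the line term at an adjusted p below 0.1 were not planned either. With 1 residual degree of freedom and 4 libraries, every count rests on the spread between libraries of a state, at a depth of 17826529 to 20774655 normalised reads. Over the alternatives, 9298 to 13824 genes passed for BQ-labelled against control-labelled libraries, against 12959. Requiring 2-fold as well left 7829, by construction. Transcripts in place of genes gave 16774 of 55869. Of the genes past the threshold, 51.6% were higher, 58.9% with equal totals, 59.5% with TPM and 50.2% with median-of-ratios factors. Lower ones prevailed without the library labelled MCF7BQ (47.2% higher) or ZR75BQ (48.0%) and among transcripts (8050 higher, 8724 lower). Without the line term 12939 genes passed, 12650 of them shared. The pairing follows the cell line in the labels and no replicate number links libraries further. Fits on 3 libraries gave 9298 to 11190 genes; they also lack the line term, and the state with 2 libraries alone gives their spread, so the fall cannot be laid on any library. Over the alternatives, the log2 difference of NCOR2 stayed between -0.952 and -1.226. The line term gave 0 genes in the 9 alternatives run for it, which hold no leave-one-out fit. In each, a difference seen in 1 state only counts in part as error, so 0 genes does not show that the lines are alike.

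The named genes were chosen mostly for large differences or small p in the main fit, which favours stability. They kept their side of the threshold and direction in 2230 of 2257 alternative results, and none reversed. MT-CO2, MT-CYB, MT-ND3, MT-ND5, OAS3, HLA-B, HLA-C, ASNS, ABCG2 and RPE did not pass in at least 1 of those fits, nor ITGAM and VWF with TPM, and the cause was not tested. Between the control-labelled libraries, 574 genes became 184 at 5 reads per 1000000, 1015 with the 10-read filter alone and 1198 at 1.5-fold. Between the BQ-labelled libraries, 131 became 83 with 5 added reads, 16 at 5 reads per 1000000, 383 with the 10-read filter alone and 502 at 1.5-fold. These settings change the genes compared, the shrinkage of low genes or the size required, by construction. The correlation of the pairs was 0.9846 at 5 reads per 1000000, 0.9689 and 0.9776 with 0.5 and 5 added reads, and 0.976 without interferon-stimulated genes. By camera 6 lists passed, 10 with equal totals and 0 with an estimated correlation, a repeat on 1 residual degree of freedom. By fry, which asks another question, 19 passed. DESeq2 and edgeR with TMM or robust spread were not run, because the values are not counts, and limma without trend or with robust spread stood in.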

Other observations

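Counts here are of genes past the limma threshold in the BQ-labelled against the control-labelled libraries, with those adjusted over the list alone in brackets where they differ. No list in the first 3 paragraphs here passed camera at an adjusted p of 0.05 on the deposited scaling. With equal totals, NRF2 targets, NF-kB targets, IL-6/STAT3 genes and replication-dependent histones did (adjusted p = 0.0370 each). The lists' adjusted p was 0.823 or more with an estimated correlation. Hypoxia-induced genes were higher in 11 of 15 cases and lower in 2, with a median log2 difference of 1.29, although ANGPTL4 (3.42 and 4.86 TPM in the control-labelled libraries) was listed at 0 in both BQ-labelled ones. NRF2 targets were lower in 11 of 18 cases and higher in 4 (median -0.68). NQO1, a quinone reductase gene, fell from 1295 ± 10.3 to 10.6 ± 1.95 TPM and G6PD, which opens the pentose phosphate pathway, from 631 ± 71.8 to 75.8 ± 0.276 TPM. Of 7 pentose phosphate genes 5 were lower (median -0.53). Glycolysis genes split, 10 (11) higher and 8 lower of 20 (median 0.29), and LDHB rose from 3.65 ± 0.665 to 1428 ± 45.6 TPM. The nuclear-encoded respiratory chain split 6 higher and 8 lower of 19.

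NF-kB targets were lower in 9 of 12 cases and higher in 3 (median -2.93), and IL-6/STAT3 genes were lower in 9 of 12 and higher in 2 (median -1.59). NFKBIA fell from 185 ± 20.5 to 16.2 ± 1.82 TPM. Immediate early genes split 7 (9) higher and 7 lower of 16, with a median of 0.46 and a mean of -0.96. Antigen presentation genes split 5 higher and 2 (4) lower of 9. The medians of the last 2 lists, like that of the interferon-stimulated genes, were higher in the library labelled ZR75 than in MCF7 (log2 ratios of 0.58 and 0.66). p53 targets were lower in 11 of 19 cases and higher in 1 (median -0.45), and unfolded protein and integrated stress response genes were higher in 10 of 17 and lower in 5 (median 0.23). Growth factor receptors and ligands split 6 higher and 8 lower of 16, with a median of -0.79 and ERBB3 falling from 91.5 ± 3.39 to 2.10 ± 0.12 TPM. BCL2 family members were lower in 7 of 12 cases and higher in 1 (median -0.52). WNT targets were higher in 7 of 9 cases and lower in 1 (median 1.26), with LEF1 rising from 1.42 ± 0.184 to 27.5 ± 2.21 TPM. NOTCH targets split 2 higher and 4 lower of 7, with a median of -1.02 and a mean of 0.26, and HEY1 rose from 0.445 ± 0.0636 to 156 ± 1.70 TPM.

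Stem-like markers were higher in 2 and lower in 4 of 8 cases (median -0.95), and CD44 (138 and 149 TPM in the control-labelled libraries) was listed at 0 in both BQ-labelled ones. Basal and myoepithelial markers were lower in 5 of 9 cases and higher in 2 (median -3.30). Retinoid-induced genes were higher in 6 of 10 cases and lower in 2 (median 2.07). Replication-dependent histones were lower in 7 of 9 cases and higher in 1 (median -2.60). These libraries hold polyadenylated RNA, so histone transcripts without a poly(A) tail are not covered. Cell cycle genes split 10 higher and 7 lower of 20 (median 0.14), ribosomal proteins 12 higher and 5 lower of 20, and housekeeping genes 3 higher and 9 (10) lower of 13. Cholesterol genes split 4 higher and 10 (9) lower of 20, androgen-induced genes 3 higher and 5 (4) lower of 13, ABC drug transporters 3 and 3 of 9, and immune cell markers 1 and 1 of 5. With equal totals the counts higher and lower became 5 and 10 for p53 targets, 11 and 1 for stress response genes, 11 and 7 for the respiratory chain and 8 and 5 for cholesterol genes. On log2(TPM + 1) the medians were over 1.5 times smaller in size for basal markers (-0.56), NF-kB targets (-1.18), IL-6/STAT3 genes (-0.87), growth factor genes (-0.45), BCL2 family members (-0.31), pentose phosphate genes (-0.31) and housekeeping genes (-0.20 against -0.44). They were over 1.5 times larger for cell cycle genes (0.36), glycolysis genes (0.53), stress response genes (0.51), antigen presentation genes (0.64 against 0.40) and ribosomal proteins (0.52 against 0.29). The medians of the androgen, cholesterol, immune cell and respiratory chain lists change sign with the scaling. The endothelial list had 1 tested member, VWF, and was not tested.

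A hypothesis about cell identity was then tested. The CDKN2A test was chosen after its values had been seen, and the others were predicted before. If the library labelled MCF7BQ were MCF-7 with the transgene, CDKN2A and its neighbour MTAP, known as deleted in MCF-7, should stay under 1 TPM. They were at 469.09 and 59.44 TPM there, which argues against it, though MTAP was not below 1 TPM in the library labelled MCF7 either (2.0 TPM). With equal totals 12983 genes passed the threshold. That scaling moved the median gene by only 0.19 log2, so the count could hardly have fallen, and the test says little on the authors' scaling as a cause. A constant per library moves all its genes the same way, whereas 1259 genes were at least 10-fold higher and 1316 at least 10-fold lower. Of 9 genes listed as markers of embryonic kidney cell lines, 8 were at least 4-fold higher and above 1 TPM in both BQ-labelled libraries. Of the same 9, 1 was also above 1 TPM in a control-labelled library. The counts go with the hypothesis that the BQ-labelled libraries come from such a line. IRS4 and LIN28B of that list had been seen before it was made, PAX2 (1.52 and 0.72 TPM) was the exception, and none of the 9 was in another list. In the control-labelled libraries CDKN2A was low in both, at 0.33 (MCF7) and 0.21 TPM (ZR75). Of 14287 genes, 46 were at least 2-fold lower and 528 higher in the library labelled ZR75. These values do not settle whether the control-labelled libraries (r = 0.971) come from 2 lines, which stays open as well. If they do not, the line term and n = 2 describe libraries rather than lines. Whether cells, tubes or files were exchanged, whether other lines would match as well, and what the variant does in luminal cells stay open.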
